A study of Sus scrofa domesticus with 4 samples.

How the data were processed

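Total RNA of the anterior pituitary was isolated with a spin column kit and had an RNA integrity number between 7.5 and 10, per the labels' protocols. Labelled cRNA of 1 pregnant and 1 cyclic gilt was hybridised together on each of 4 Agilent porcine arrays, which lay on 1 slide and were scanned in 1 run, so there was no batch to fit. The labelling protocol's text names a single orientation of the dyes, while the label fields of the samples give Cy3 to the pregnant animal on arrays 1 and 3 and Cy5 on arrays 2 and 4. The label fields were followed. A single orientation would turn arrays 2 and 4, and the group could then not be told from the dye. Fitted without a dye term, that assignment gave 0 features at the adjusted threshold, 1552 at the looser one and 1 shifted list, which does not settle which orientation holds. Spots were read at 5 micron with Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited scanner files hold the median pixel intensity of each spot and of its local background in both channels, and processed intensities after background subtraction, detrending and dye normalization by that software, per the file headers. The authors' value table holds log2 ratios with no statement of how they were made. For all 43553 probes spotted once, its values equalled log2 of processed red over processed green within 0.001 on each array, with the sign turned on arrays 1 and 3, which makes its direction pregnant over cyclic by the label fields. Its column medians were 0.150, -0.0102, 0.0650 and -0.0726, so no centring beyond the scanner software's was found.

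Ratios were computed in R 4.3.3 with limma 3.58.1, data.table (version 1.17.8) and jsonlite 2.0.0. Background was corrected by normexp with an offset of 50 on the median foreground and median background intensity. The fixed design had named the mean foreground, which the files used here do not hold. The normexp parameters of each channel were estimated without the spots whose signal or background the scanner software had marked as outliers in that channel, between 377 and 3480 spots of 45220. Every result was first computed with parameters from all spots. In 5 of the 8 channels the estimated background spread was then far larger than without the marked spots, with 6439 in the red channel of array 4, 1071 and 1770 on array 2 and 94.5 and 67.0 on array 1, against 1.17 to 2.51 over the 8 channels. Some spots there had a background far over their signal, the lowest difference being -996800 in the red channel of array 4. Leaving out that spot alone brought the spread of its channel to 10.53. On array 2 leaving out the lowest spot left 386.1 and 23.67 and leaving out the lowest 10 left 4.76 and 1.89, and on array 1 these were 73.42 and 42.22 and then 9.264 and 2.787. That test was added after the change. The median corrected intensity of that red channel was 4956 with all spots and 124.2 without the marked ones. The estimate was therefore changed after results had been seen, on the parameters alone and before any call under the new estimate was known, and the first version is kept as an alternative.

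Ratios were then normalized within each array by loess with a span of 0.3, in which 1417 control spots had weight 0. Spots marked as outliers (26 to 63 per array) were left out, spots of a probe were averaged, and every ratio was turned to pregnant over cyclic. Probes well above background in at least 4 of the 8 channels were kept, 25138 of 43603. Probes were named through their RefSeq accession by the RefSeq names of the Sscrofa11.1 assembly, and 6700 probes carried 1 symbol each (3029 genes), among them 6515 of 6624 with a RefSeq mRNA accession and 182 of 498 with a RefSeq model accession. The remaining probes, among them 8889 with an Ensembl transcript, 12986 with a consensus sequence and 5224 with a probe number alone, kept the file's identifier and are unnamed here. The probe with the highest mean intensity stood for a gene, which left 18852 features, 2406 with a symbol. Where other probes of a gene given in the Results had the opposite sign, the text there says so. Of the genes given only under the dependence on processing, AURKB had 1 of its 2 other probes of the same sign and NEFL 3 of its 4.

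For each feature limma's lmFit and eBayes estimated the pregnant over cyclic ratio beside a gene-specific dye effect, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. A looser count took an unadjusted p under 0.05 with a fold of at least 1.2. Lists of genes were tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, whose directional p asks whether a list's genes move one way and does not compare them with other genes. Lists needed 3 members, and 26 of 27 had them. Single members were also adjusted over their list alone, which does not correct for the number of lists. A two-sided exact sign-flip test of a list's 4 array means has 8 assignments and cannot go below 0.125. Genes that had entered lists through wrong older symbols were taken out. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 10 genes on each side with the lowest unadjusted p, 1 sign on 4 arrays and a fold of at least 1.2, filling the places left by genes past the threshold, every hormone gene, up to 4 members of each list with the lowest unadjusted p, and the 2 brightest members of lists of other cell types. That rule had for a time been narrowed to members under an unadjusted p of 0.05 and was put back as written. Some genes that the rule names are not reported here.

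The steps were tested on simulated data with each feature's spread as limma moderated it, in 20 sets of 18852 features with 200 changed, 50 per fold. At the adjusted threshold limma recovered 0.5% of features changed by 1.2-fold, 24.3% at 1.5-fold, 93.1% at 2-fold and 100% at 4-fold, with a mean of 10.05 false calls per set. That recovery depended on the changes planted and on the moderated spread, and it does not carry over to the data. There PTGDS, with a fold of 0.500, had a limma adjusted p of 0.647. At the looser threshold, an unadjusted p under 0.05 with a fold of at least 1.2, limma recovered 42.9%, 96.5%, 99.7% and 100%, with a mean of 825.35 false calls per set. A list of 26 genes shifted by 0.2 was called by camera in 20 of 20 sets, with 3 calls of other lists in all. The simulated noise was drawn independently for each feature. In the data camera estimated a correlation of 0.11 among the interferon-stimulated genes and 0.19 among the collagen and stromal matrix genes. The list calls of the simulation therefore do not carry over to correlated genes. Alternatives covered the dye term, the background correction, the scanner software's processed values and the authors' value table, median centring, separate channels, the filter on dim probes, the mean of a gene's probes, the variance model, array weights, the set test, the threshold and leaving out each array. With 1 array left out the dye term stayed in the fit. The array left alone in its dye orientation then counted as much as the others together. A narrower loess, the removal of the brightest features, the background parameters from all spots and the hormone list without TSHB were added after the data were seen.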

Results

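Gene expression was measured in the anterior lobe of the pituitary gland of 8 gilts, young female pigs of a Large White by Polish Landrace cross. Early pregnancy, around the time when the conceptuses attach to the uterus, was compared with the same days of the estrous cycle. The pregnant group held 4 animals and the cyclic group held 4 animals, all collected on days 15 to 16. Each of 4 two-colour oligonucleotide arrays carried the RNA of 1 pregnant and 1 cyclic animal, so an array was 1 independent pair. Pregnant RNA carried the dye Cy3 on arrays 1 and 3 and the dye Cy5 on arrays 2 and 4, per the label fields of the samples. Between 50.4% and 60.4% of the pregnant channel's spots and between 52.5% and 66.5% of the cyclic channel's spots were well above background, the highest share being the cyclic channel of array 1. No spot was saturated (0 spots on each array). Ratios are given as log2 of pregnant over cyclic, with the standard error of the limma fit over 4 arrays, and the number of arrays limits their precision. That standard error is what remains after the gene-specific dye effect, with a variance that limma moderates across features. It can be much smaller than the spread between arrays.

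Which transcripts differed between the pregnant and the cyclic gland was asked of 18852 features, of which 2406 carried a gene symbol. CARTPT, which encodes the CART neuropeptide precursor, had the lowest unadjusted p of the named genes at -1.43 ± 0.18, with ratios below 0 on 4 of 4 arrays. PTGDS, the lipocalin-type prostaglandin D synthase, stood at -0.999 ± 0.15 and was also lower on 4 of 4 arrays. ABHD5, the coactivator of adipose triglyceride lipase, stood at 0.81 ± 0.10 and KLF6, a zinc finger transcription factor, at 0.81 ± 0.12, both higher on 4 of 4 arrays. None of these genes passed adjustment over all features (limma with Benjamini-Hochberg adjustment, adjusted p = 0.620 for CARTPT and ABHD5, and 0.647 for PTGDS and KLF6).

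The other genes of lowest unadjusted p on the higher side included DDX46, an RNA helicase of the splicing machinery, at 0.70 ± 0.11, and SNRPD3, a core protein of the spliceosomal particles, at 0.48 ± 0.11. ACADM, the medium-chain acyl-CoA dehydrogenase of fatty acid oxidation, stood at 0.49 ± 0.09, and its 6 other probes shared its sign. CD274, the ligand of the inhibitory receptor PD-1, stood at 0.49 ± 0.10. KIT, a receptor tyrosine kinase, stood at 0.57 ± 0.12, with single arrays between 0.10 and 1.24. PNPLA4, a lipid hydrolase, stood at 1.19 ± 0.28, with array 3 at 0.08. THAP2 stood at 0.60 ± 0.11, with array 2 apart from the other 3 arrays at 0.35. On the lower side were DDO, the D-aspartate oxidase, at -0.68 ± 0.10, HYAL2, a hyaluronidase, at -0.69 ± 0.12, and SELENOM, a selenoprotein of the endoplasmic reticulum, at -0.92 ± 0.22. Single arrays were at -0.99, -0.29, -1.09 and -0.34 for DDO and between -0.98 and -0.24 for HYAL2. TGFBR3, the betaglycan coreceptor for inhibin and TGF-beta, stood at -0.44 ± 0.10, and SPARC, a matricellular glycoprotein, at -0.50 ± 0.12, with its 6 other probes of the same sign. IRF7, an interferon regulatory factor, stood at -0.68 ± 0.16, CUEDC1 at -0.64 ± 0.12 and PRR5 at -0.49 ± 0.12. All of these genes had 1 sign on all 4 arrays, by the rule that named them, and limma adjusted p between 0.620 and 0.647.

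**Figure D1:**
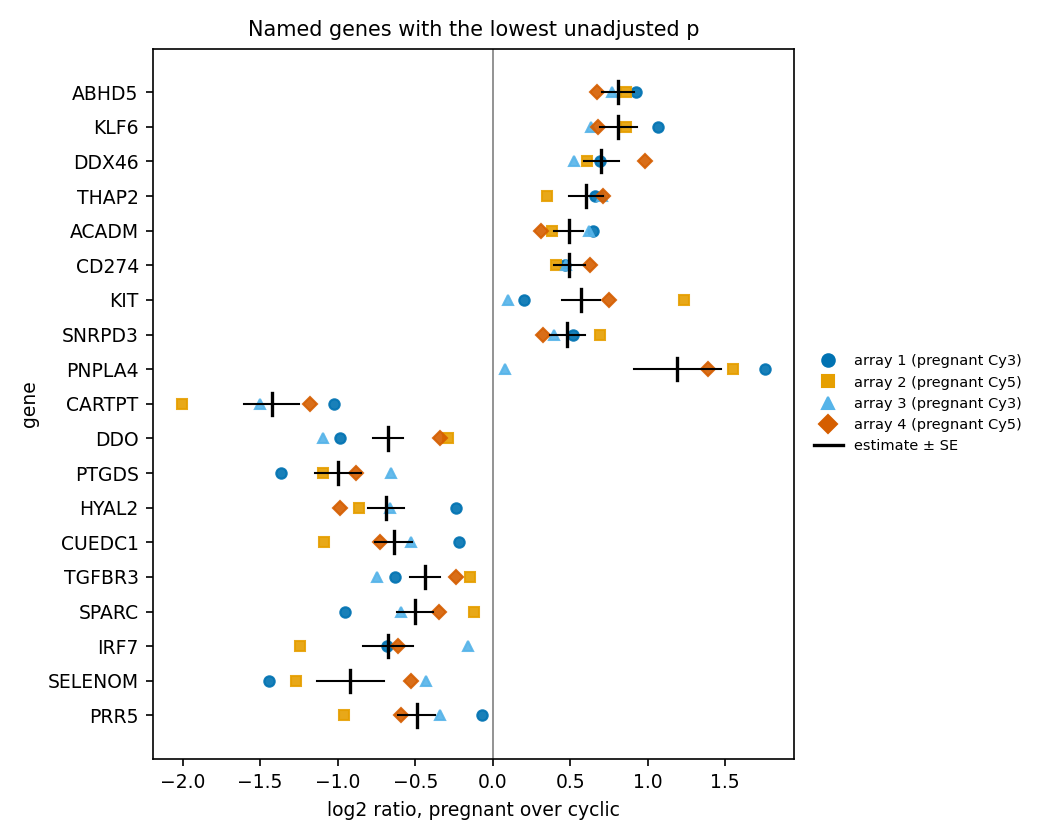
Log2 ratio of pregnant over cyclic (horizontal axis) for the genes named in the text with the lowest unadjusted p on each side; markers are the 4 arrays, black ticks the limma estimates and bars their standard errors. CARTPT lies below -1.02 on every array and ABHD5 above 0.67 on every array.

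No feature passed an adjusted p of 0.05 (0 of 18852 by limma, smallest adjusted p = 0.135), and 0 passed at 0.1. At an unadjusted p under 0.05 there were 1360 features, 7.21% of those tested, where 942.6 would come by chance. With a fold of at least 1.2 as well, 1323 features remained, 553 higher and 770 lower in pregnant animals, of which 90 and 106 had a gene symbol. This count was 639 without array 1, 617 without array 2 and 2174 without array 4, and without array 2 the balance turned, with 355 higher and 262 lower, against 623 and 1551 without array 4. With background parameters from all spots, as first computed, it was 473, of which 293 were shared, and with median centring in place of loess 19.3% were higher, against 41.8%. Without the dye term limma also called 0 features, with 1080 at an unadjusted p under 0.05, and limma's separate-channel fit called 3, ABHD5 among them (adjusted p = 0.0237). A smaller background offset called 2 features, neither with a gene symbol. All 4 arrays had 1 sign for 2613 features, 13.9% of those tested, where chance gives 12.5%.

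Arrays resembled each other little in either direction. Across features, which are not independent replicates, the mean correlation between pairs of arrays was 0.0523 for pregnant over cyclic and 0.0887 for red over green. Single pairs of turned ratios ranged from -0.272 for arrays 2 and 3 to 0.322 for arrays 2 and 4.

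Of the 7 hormone genes that define the secretory cell types, 6 had an estimate below 0, and several differed widely between arrays. That tally depended on the setting: with background parameters from all spots PRL, POMC and CGA stood above 0, at 0.17, 0.36 and 0.36, without array 3 GH1 stood at 0.02 and FSHB at -0.31, and without array 4 TSHB stood above 0. LHB, the beta subunit of luteinizing hormone, stood at -0.42 ± 0.15 and was lower on 4 of 4 arrays, with an unadjusted p of 0.0365. PRL, prolactin, stood at -0.31 ± 0.18, with arrays 1, 2 and 4 below 0 and array 3 at 0.19. GH1, growth hormone, stood at -0.53 ± 0.38, and array 3 alone was at -2.50 while array 2 was at 0.74. POMC, the precursor of adrenocorticotropin, stood at -0.11 ± 0.12 and CGA, the common glycoprotein alpha subunit, at -0.10 ± 0.12. On arrays 1 to 4 POMC was at -0.55, 0.64, -0.85 and 0.31 and CGA at -0.54, 0.63, -0.94 and 0.46. For both, red exceeded green on all 4 arrays, so their ratios followed the dye. Both were brighter than a mean log2 intensity of 16, where the median ratios of all features were -0.45, 0.18, -0.08 and 0.20. PRL, GH1 and LHB lay in this range as well. On arrays 1 to 4 LHB was at -0.78, -0.61, -0.19 and -0.12. FSHB, the beta subunit of follicle-stimulating hormone, stood at 0.41 ± 0.50, with array 3 at 2.53 and array 4 at -0.84. TSHB, the beta subunit of thyrotropin, had the widest spread of the 7, at -1.10 ± 1.37, with 4.48 on array 2 and -1.67, -3.03 and -4.20 on arrays 1, 3 and 4. Of the 7 genes 0 passed limma's adjusted threshold and 0 adjusted over the list alone, where LHB was at an adjusted p of 0.256, and LHB was the 1 gene with an unadjusted p under 0.05. The list's mean was -0.31 (camera adjusted p = 0.338), from array means of -0.71, 0.84, -0.68 and -0.68, so array 2 went the other way. Without array 2 the list stood at -0.69 (camera adjusted p = 0.0101), without array 4 at 0.0690, and with background parameters from all spots at 0.0638. In the fit without array 4, which kept the dye term, array 2 counted as much as arrays 1 and 3 together. TSHB carried much of the changes with 1 array left out, but not the change with all spots. Over the other 6 genes the mean was -0.18 (camera adjusted p = 0.343), with array means of -0.55, 0.23, -0.29 and -0.09, and it was -0.26 and not called without array 2 (adjusted p = 0.0967), -0.10 without array 4 and 0.22 with background parameters from all spots. That removal was chosen after the values were seen.

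**Figure D2:**
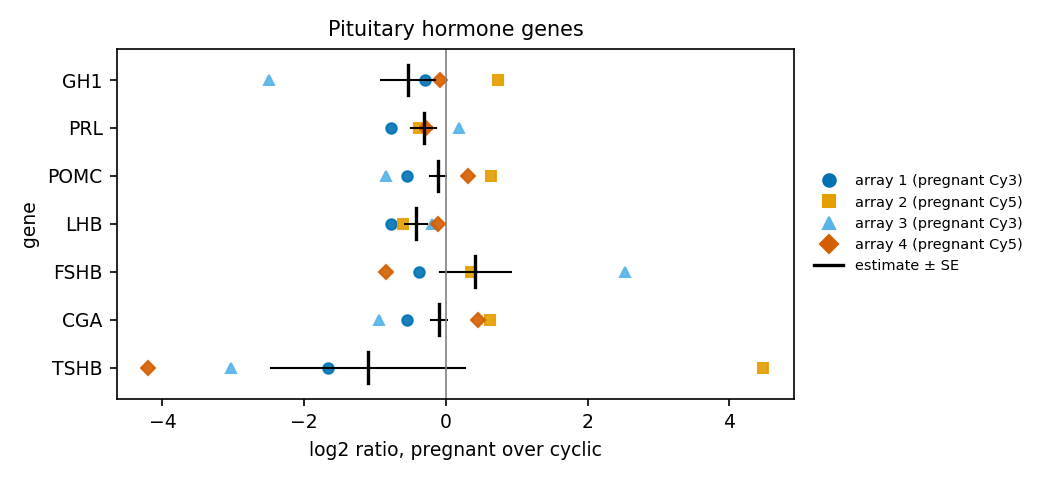
Log2 ratio of pregnant over cyclic (horizontal axis) for the 7 pituitary hormone genes; markers are the 4 arrays, black ticks the limma estimates and bars their standard errors. TSHB spans from -4.20 on array 4 to 4.48 on array 2, and LHB lies below 0 on 4 of 4 arrays.

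Interferon-stimulated genes were higher in the pregnant animals as a group. Of the 26 members tested, 23 had an estimate above 0, and the list's mean was 0.20 with a median of 0.26. IFIH1, a cytosolic sensor of viral RNA, stood at 0.30 ± 0.11, and PSMB9, a subunit of the immunoproteasome, at 0.27 ± 0.10, each above 0 on 4 of 4 arrays. IRF7 went the other way at -0.68 ± 0.16, below 0 on 4 of 4 arrays. Members at an unadjusted p under 0.05 numbered 4 higher and 1 lower, and 0 passed limma's adjusted threshold, over all features or adjusted over the list alone. Camera with its preset correlation called the list (adjusted p = 1.22e-04), and the call was lost at adjusted p = 0.964 with an estimated correlation. Fry gave an adjusted p of 0.682. The list's mean was 0.24, 0.28 and 0.45 on arrays 1 to 3 and -0.16 on array 4, and an exact two-sided sign-flip test of the 4 array means gave p = 0.25, where 4 arrays cannot give less than 0.125. Without array 2 the shift was 0.09, still called by camera at an adjusted p of 0.0498, and without array 4 it was 0.31. These fits kept the dye term, so without array 2, array 4 counted as much as arrays 1 and 3 together.

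Collagen and stromal matrix genes were lower in the pregnant animals as a group. Of the 18 members tested, 15 had an estimate below 0, and the list's mean was -0.16 with a median of -0.17. SPARC had the lowest p at -0.50 ± 0.12, and COL5A1, a chain of type V collagen, stood at -0.34 ± 0.09, although its 1 other probe had the opposite sign. COL5A2, the partner chain, stood at -0.26 ± 0.10 and MYL9, a smooth muscle myosin light chain, at -0.30 ± 0.12. The brightest members were TIMP1, an inhibitor of matrix metalloproteinases, at -0.06 ± 0.15, and MMP2, a gelatinase, at -0.17 ± 0.10. At an unadjusted p under 0.05 were 2 members, both lower, and 0 passed limma's adjusted threshold, over all features or adjusted over the list alone. Camera with its preset correlation called the list (adjusted p = 0.0457), and the call was lost at adjusted p = 0.964 with an estimated correlation. Fry gave an adjusted p of 0.682. The list was below 0 on 4 of 4 arrays, with array 1 apart at -0.38 and the others between -0.09 and -0.07. The exact two-sided sign-flip test gave p = 0.125, the smallest that 4 arrays allow, and an adjusted p of 0.675 over the lists. The same test also gave 0.125 for the lists of lineage transcription factors, of receptors, of granins and neuropeptides and of cholesterol synthesis. The call ended without array 1, at -0.08 (adjusted p = 0.299), without array 4, at -0.16 as with all arrays (adjusted p = 0.544), and under several other ways of preparing the values, among them no dye term, at the same -0.16 (adjusted p = 0.0696), and separate channels (adjusted p = 0.0510).

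**Figure D3:**
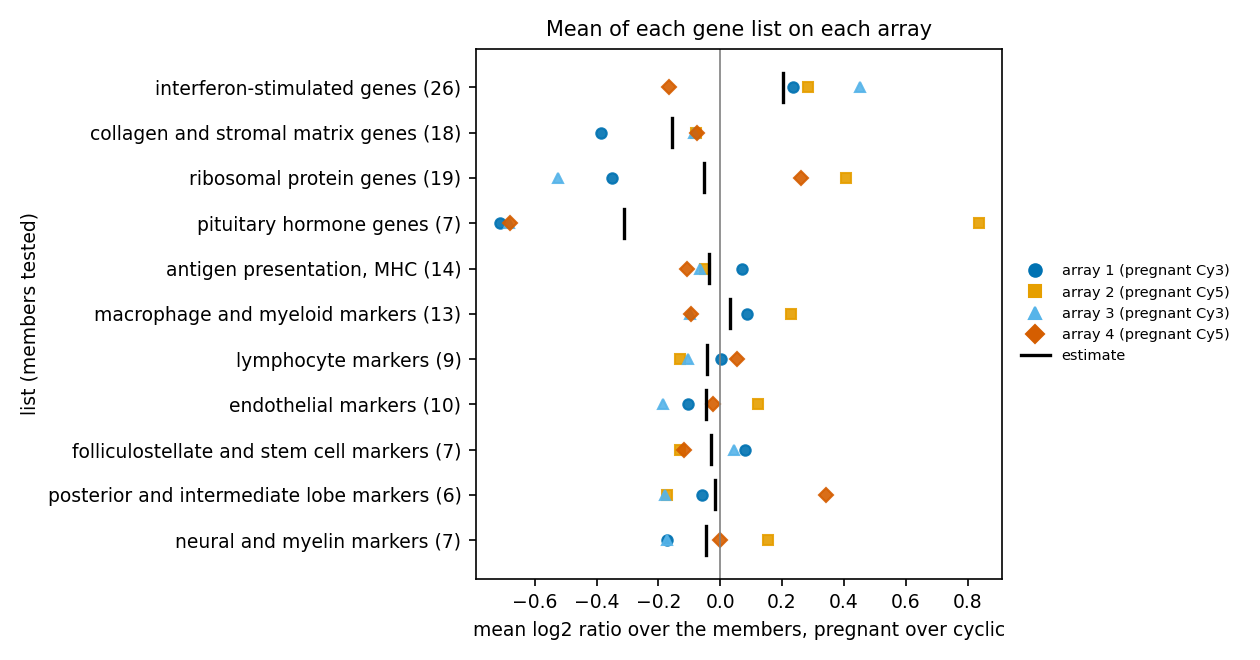
Mean log2 ratio of pregnant over cyclic over the members of a list (horizontal axis), for 11 of the 27 lists with the number of members tested in brackets; markers are the 4 arrays and black ticks the estimates. Interferon-stimulated genes have a mean of 0.20 with array 4 below 0, and ribosomal protein genes lie below 0 on arrays 1 and 3 and above 0 on arrays 2 and 4.

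These were the 2 lists called by camera among the 26 with enough members to test, and 0 lists were called by camera with an estimated correlation, where every list had an adjusted p of 0.964, or by fry, where the smallest adjusted p was 0.638. Without array 3 camera called 4 lists, without arrays 1 or 2 it called 3 each, and without array 4 it called 1. The values of the other 23 lists, besides the hormone genes above, follow by theme. None passed camera's adjusted threshold.

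Among genes of peptide secretion, CARTPT led the granins and neuropeptides, and CHGA, the chromogranin A of secretory granules, stood at -0.56 ± 0.19 and below 0 on 4 of 4 arrays. CHGB, its relative, stood at -0.16 ± 0.10, and GNRH1, whose cyclic channel was above background on 3 of 4 arrays, at 0.44 ± 0.19. Of the 14 members 2 were at an unadjusted p under 0.05, both lower, and CARTPT alone passed when adjusted over the list alone (adjusted p = 0.00536). The list's mean was -0.15 (camera adjusted p = 0.808), with array means of -0.14, -0.19, -0.15 and -0.12. For prostaglandin synthesis and receptors, PTGDS passed when adjusted over the list alone (adjusted p = 0.00665) as the 1 of 7 members that did. PTGS2, the inducible cyclooxygenase, stood at 0.46 ± 0.27, with 1.72 on array 1, and PTGES, a prostaglandin E synthase, at -0.16 ± 0.13, with array 3 apart at -0.58. Its mean was -0.17 (camera adjusted p = 0.338). Without array 1 camera called it at -0.28 (adjusted p = 0.0128), and without array 3 it was -0.06 and not called. In the IGF system, IGFBP5, an IGF-binding protein, stood at -0.76 ± 0.22 and was lower on 4 of 4 arrays as the 1 of 11 members at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. IGF2 stood at -0.38 ± 0.21 and IGF2R, with array 2 apart at -0.37, at -0.17 ± 0.10, above background in 3 of the 4 pregnant channels. The mean of this list was -0.11 (camera adjusted p = 0.808).

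Receptors of the hypothalamic and pituitary axis gave GHR, the growth hormone receptor, at 0.36 ± 0.12 and above 0 on 4 of 4 arrays. SSTR2, a somatostatin receptor above background in 3 of the 4 pregnant channels, stood at -0.32 ± 0.12, GHRHR at -0.64 ± 0.29 and GNRHR, the receptor of gonadotropin-releasing hormone, at -0.65 ± 0.30. Of 13 members 1 was higher and 1 lower at an unadjusted p under 0.05, with 0 adjusted over the list alone and a list mean of -0.13 (camera adjusted p = 0.767). Of the steroid receptors and coregulators, ESR1, the estrogen receptor alpha, stood at -0.52 ± 0.15 with array 4 at 0.03, and its 2 other probes had the opposite sign. PGR, the progesterone receptor, stood at -0.55 ± 0.21, from -1.83 on array 3 to 0.40 on array 4, and FKBP4 at -0.33 ± 0.14. Of 12 members 2 were at an unadjusted p under 0.05, both lower, 0 passed adjusted over the list alone, and the mean was -0.10 (camera adjusted p = 0.845). Those same 2 genes, ESR1 and PGR, were the members of the estrogen-responsive list at that threshold, of 10 tested. GATA3 stood at 0.29 ± 0.13 in that list, 0 passed adjusted over the list alone, and the mean of -0.05 and the median of 0.07 differed in sign, camera's direction being upward (adjusted p = 0.859). Of 7 lineage transcription factors 0 were at an unadjusted p under 0.05 and 0 passed adjusted over the list alone, with GATA2, a factor of the gonadotrope and thyrotrope lineages, at -0.65 ± 0.28, of which array 1 alone was at -1.93 and the pregnant channel was above background on 3 of 4 arrays. NR5A1, steroidogenic factor 1, stood at -0.38 ± 0.17, SOX2, with array 2 apart at -0.45, at -0.14 ± 0.11, and the list's mean was -0.18 (camera adjusted p = 0.725).

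In activin, inhibin, BMP and TGF-beta signalling, TGFBR3 was the 1 of 22 members at an unadjusted p under 0.05. FST, the activin-binding follistatin, stood at 0.28 ± 0.13, though its 1 other probe had the opposite sign, BMP4 at -0.28 ± 0.12 and TGFB1 at 0.31 ± 0.15. The list's mean of 0.02 and median of -0.01 differed in sign, with camera's direction upward (adjusted p = 0.808), and 0 passed adjusted over the list alone. Among adipokines, orexins and their receptors, RARRES2, which encodes chemerin, stood at -0.34 ± 0.10 and ADIPOR1, an adiponectin receptor, at -0.22 ± 0.10, both lower on 4 of 4 arrays. HCRT, the orexin precursor, stood at -0.33 ± 0.16 and NAMPT, which encodes visfatin, at 0.18 ± 0.12. RARRES2 was the 1 of 9 members at an unadjusted p under 0.05, 0 passed adjusted over the list alone, and the mean of -0.02 and median of 0.03 differed in sign, with camera's direction downward (adjusted p = 0.961). In cholesterol synthesis and uptake, MSMO1, a sterol methyl oxidase, stood at 0.50 ± 0.14, CYP51, the lanosterol demethylase, at 0.33 ± 0.10 and SQLE, squalene epoxidase, at 0.25 ± 0.12, each above 0 on 4 of 4 arrays. The first 2 of these were the members at an unadjusted p under 0.05, of 13 tested, 0 passed adjusted over the list alone, and the list's mean of 0.09, above 0 on 4 of 4 arrays, missed camera's threshold (adjusted p = 0.338).

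Immune genes outside the interferon list lay on both sides of 0. In antigen presentation, CD74, the invariant chain, stood at -0.63 ± 0.21 and SLA-6, a class I gene, at -0.52 ± 0.15, both lower on 4 of 4 arrays, while B2M, the class I light chain, stood at 0.19 ± 0.10. The first 2 were the members at an unadjusted p under 0.05, of 14 tested, 0 passed adjusted over the list alone, and the mean of -0.04 and median of 0.06 differed in sign, with camera's direction upward (adjusted p = 0.859). Among macrophage and myeloid markers, AIF1 stood at 0.38 ± 0.14, above 0 on 4 of 4 arrays, FCGR1A at 0.31 ± 0.14, CD163, a scavenger receptor, at -0.37 ± 0.21, and the bright C1QB, a complement chain, at -0.02 ± 0.10. AIF1 was the 1 of 13 members at an unadjusted p under 0.05, 0 passed adjusted over the list alone, and the mean was 0.03 (camera adjusted p = 0.725). Among lymphocyte markers, CD79A, of the B cell receptor, stood at -0.69 ± 0.25 and was the 1 of 9 at an unadjusted p under 0.05. GZMB stood at -0.24 ± 0.12, CCL5 at 0.16 ± 0.10 and CD8A, above background on 2 of 4 arrays in each group and with array 3 apart at -0.04, at 0.23 ± 0.11. The mean of -0.04 and median of 0.00272 differed in sign, with camera's direction upward (adjusted p = 0.859), and 0 passed adjusted over the list alone.

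Of the immediate-early genes, KLF6 passed when adjusted over the list alone (adjusted p = 0.00922), and CTGF, a matricellular growth factor, stood at -0.34 ± 0.12. NR4A3, an orphan nuclear receptor, stood at 0.65 ± 0.65, from -1.16 on array 3 to 2.95 on array 4 and with 1 of its 3 other probes of the opposite sign, and KLF2, whose 1 other probe had the opposite sign, at 0.09 ± 0.10. Of 10 members 1 was higher and 1 lower at an unadjusted p under 0.05, and the list's mean was 0.12 (camera adjusted p = 0.725), with 0.40 and a call without array 3 (adjusted p = 0.0381) but reversed to -0.16 without array 1 and -0.12 without array 4. Of 12 heat shock genes HSPB1, a small chaperone, was the 1 at an unadjusted p under 0.05, at -0.46 ± 0.12 and lower on 4 of 4 arrays. HSPH1 stood at 0.38 ± 0.25, 0 passed adjusted over the list alone, and the list's mean was 0.05 (camera adjusted p = 0.808), with 0.21 and a call without array 3 (adjusted p = 0.0381) but reversed to -0.12 without array 1 and -0.02 without array 2. In the unfolded protein response, CALR, calreticulin, stood at -0.51 ± 0.27, DNAJC3 at -0.36 ± 0.18 and ATF4 at -0.18 ± 0.10, with 0 of 9 at an unadjusted p under 0.05, 0 adjusted over the list alone and a mean of -0.17 (camera adjusted p = 0.338), which was -0.23 and called with the mean of a gene's probes (adjusted p = 0.0468) and -0.08 and not called without array 1 (adjusted p = 0.538). Of 8 cell cycle genes 0 were at an unadjusted p under 0.05 and 0 passed adjusted over the list alone, with TOP2A at 0.12 ± 0.27, CCNB1 at 0.17 ± 0.23 and AURKA, above background in 3 of the 4 pregnant channels, at -0.13 ± 0.10, and a mean of 0.02 (camera adjusted p = 0.927), with 0.22 and a call without array 1 (adjusted p = 0.0498) but reversed to -0.10 without array 2 and -0.17 without array 3.

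Markers of other cell types that the dissected tissue could hold also stayed short of the threshold, and 0 of them passed adjusted over the list alone. Of 10 endothelial markers 0 were at an unadjusted p under 0.05, with ENG, endoglin, at -0.40 ± 0.17, VWF at -0.24 ± 0.11, CDH5, whose 1 other probe had the opposite sign, at 0.51 ± 0.25, and a mean of -0.05 (camera adjusted p = 0.767). Of 7 folliculostellate and stem cell markers 0 reached that p, with EPCAM, an epithelial adhesion molecule, at 0.24 ± 0.12, KRT8, a keratin, at -0.28 ± 0.16, and IL6, above background on 2 pregnant and 3 cyclic channels, at -0.08 ± 0.10. Their mean of -0.03 and median of 0.00187 differed in sign, with camera's direction downward (adjusted p = 0.960). Of 6 posterior and intermediate lobe markers 0 reached it, with OXT, the oxytocin precursor, at -0.36 ± 0.16, PCSK2, above background in 3 of the 4 cyclic channels, at 0.40 ± 0.49, SLC1A3, above background on 2 of 4 arrays in each group and with array 2 apart at 0.31, at 0.10 ± 0.10, and a mean of -0.02 (camera adjusted p = 0.869). Of 7 neural and myelin markers 0 reached it, with GAD2 at -0.30 ± 0.13, GAP43, a growth cone protein, at 0.28 ± 0.14, MBP, myelin basic protein, at -0.19 ± 0.32, and a mean of -0.05 (camera adjusted p = 0.951). HBE1, an embryonic globin above background on 3 of 4 arrays in each group, was the 1 erythroid gene measured, at -0.01 ± 0.13, so that list was not tested.

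Of 19 ribosomal protein genes 0 were at an unadjusted p under 0.05 and 0 passed adjusted over the list alone, with RPL10 at -0.24 ± 0.12 and RPS18 at -0.11 ± 0.10, and a list mean of -0.05 (camera adjusted p = 0.751). With background parameters from all spots that mean was 0.277 and called (camera adjusted p = 0.00276). Of 12 oxidative phosphorylation genes SDHD, a membrane anchor of succinate dehydrogenase, was the 1 at an unadjusted p under 0.05, at 0.34 ± 0.09 and above 0 on 4 of 4 arrays, and 0 passed adjusted over the list alone. NDUFA4 stood at -0.19 ± 0.11, COX7C at -0.18 ± 0.11, and the list's mean was -0.03 (camera adjusted p = 0.859).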

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

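The leukocyte test was chosen only after the result was seen, and all tests of this part were first run on values corrected with background parameters from all spots and then repeated. The sampling of brightness-matched genes was narrowed from a wider window to the 40 nearest neighbours of each member after a result was seen, and the reading of the connective tissue test was made stricter after its standard errors were known. The numbers of features and lists under other assignments were planned.

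Of 153 results examined, 9 had 1 array so far from the other 3 that its gap exceeded Dixon's limit for 4 values. Chance does this in about 1 in 20, which is near the share found. The results also overlap, since list means include named genes. Array 2 was the distant one in 5, array 1 in 2 and array 3 in 2. The gap over the range was 0.864 for THAP2, 0.843 for SOX2, 0.846 for SLC1A3 and 0.842 for IGF2R, each with array 2 apart. It was 0.992 for GATA2 with array 1 apart, and 0.866 for CD8A and 0.891 for PTGES with array 3 apart. The pituitary hormone genes as a list had a gap of 0.979, with array 2 at 0.84 and the other 3 arrays between -0.71 and -0.68. Without TSHB, left out after its values were seen, that gap was 0.412, within the limit, so the distance of array 2 rested on 1 gene. The collagen and stromal matrix genes had a gap of 0.965, with array 1 at -0.38.

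The interferon-stimulated genes had a median of 0.26 in pregnant animals. More leukocytes in the pregnant glands would raise leukocyte markers as much. The median over 22 such markers was 0.01, and the upper limit of its central 95% was 0.128 when the markers were resampled. That interval measures spread between genes and not between animals, so it does not exclude more leukocytes. By array, the macrophage and myeloid markers had means of 0.09, 0.23, -0.10 and -0.09, and the lymphocyte markers 0.002, -0.13, -0.10 and 0.06. Macrophages and lymphocytes also express interferon-stimulated genes, and a change of such genes within them is not excluded. Of 10000 lists matched on brightness the median was -0.04 and the upper limit of the central 95% was 0.0473, against the list's mean of 0.20. The list thus lay above other features as bright, taken as independent draws. The loess step centres ratios along brightness, though not closely for features brighter than a mean log2 intensity of 16. Near this list's mean log2 intensity of 9.78, matched lists therefore lie near 0 by construction and cannot decide on a bias tied to brightness. A difference tied to pregnancy stays open as a hypothesis, with array 4 at -0.16, and an estimated correlation ended camera's call at adjusted p = 0.964.

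The collagen and stromal matrix genes had a mean of -0.16 in pregnant animals. Among lists matched on brightness, whose central 95% had a lower limit of -0.128, the list lay at percentile 0.75. Those lists also lie near 0 through the loess step and take genes as independent draws. A bias tied to brightness was therefore not decided. A smaller share of connective tissue in the pregnant samples stays open: the median of COL1A2, COL5A1, COL5A2 and DCN was below 0 on 4 of 4 arrays, but by more than its standard error on 2 of them only. A difference in the gland itself cannot be told apart from that with 4 markers, of which COL5A1 was dim and its 1 other probe had the opposite sign, and neither account was decided.

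Turning the assignment of the animals on some of the arrays gives 8 assignments, too few for a share under 0.05. The looser count was 1323 with the real assignment, and the highest other was 2359, reached with array 4 turned, with 5 of 8 giving as many. The assignment with arrays 2 and 4 turned, at 1552, was fitted without the dye term, because group and dye coincide there, and the other 7 were fitted with it. Without the dye term the real assignment gave 1063. At the adjusted threshold 8 of 8 assignments gave 0 features, so the highest other was 0. The real assignment gave 2 shifted lists, the highest other 5, and 6 of 8 gave as many.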

How the results depend on the processing

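The tests with a narrower loess (span 0.05), without features brighter than a mean log2 intensity of 16 and with normexp parameters from all spots were chosen only after the data were seen. Over 19 settings besides the one reported, 100 of 123 named genes and 13 of 26 lists kept their sign wherever they had a value. Some settings could hardly change a sign. No dye term, the variance model, array weights, separate channels, no dim filter and the removal of bright features gave estimates correlated with the reported ones at 0.9999 or more. The processed values and the value table gave the same values and count as 2 settings. The counts below therefore overstate stability. Of 493 list shifts, 442 kept direction and side of the threshold, 34 reversed (1 of them also becoming called), 6 became called in the same direction and 11 lost a call, and of 2317 values of named genes 2276, 40 and 1 did the first 3. The cause of a change was not tested unless stated. Lists on separate channels were tested with camera's pre-ranked form on the moderated statistics, a step first left out and run after the other results were seen.

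Limma called 0 features at an adjusted p of 0.05 in all settings but 2, with 617 to 2500 at an unadjusted p under 0.05, and 0 at 0.1 in the setting reported. Offset 16 called 2 features, BF192668 and TC574560, and separate channels called 3, ABHD5, TC574560 and ENSSSCT00000007604, named after their values were seen. The looser count was 473 with normexp parameters from all spots, 293 of them shared with the 1323 reported, and 617 to 2174 when 1 array was left out (639 without array 1, 617 without array 2, 2174 without array 4). Of the looser count 41.8% were higher in pregnant animals, against 19.3% with median centring, 30.7% with all spots, 57.5% without array 2, 30.5% without array 3 and 28.7% without array 4.

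Camera called 2 lists, and 1 with offset 16, without the dye term, without background subtraction, with the scanner software's processed values, with the authors' value table, with median centring, with separate channels and with all 8 channels well above background. It called 0 with an estimated correlation, as did fry, and 1 to 4 with 1 array left out (4 without array 3, 1 without array 4). The interferon-stimulated genes kept camera's call in the other settings, with a shift of 0.09 (adjusted p = 0.0498) without array 2 and 0.31 without array 4. The collagen and stromal matrix genes lost it at a shift of -0.164 with offset 16, -0.155 without the dye term, -0.139 without background subtraction, -0.168 with the processed values and with the value table, -0.206 with median centring, -0.155 with separate channels, -0.153 with all 8 channels well above background and -0.154 with the mean of a gene's probes, adjusted p running from 0.0510 to 0.168. Without 1 array the shift ran from -0.230 to -0.0804, and the call ended without array 1 and without array 4, where the shift was -0.156.

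Reversed under normexp with all spots were the lists of pituitary hormone genes (0.0638), activin, inhibin, BMP and TGF-beta signalling (-0.00337), macrophage and myeloid markers (-0.00362), folliculostellate and stem cell markers (0.0331), ribosomal protein genes (0.277, camera adjusted p = 0.00276) and oxidative phosphorylation genes (0.0184), and the genes PRL (0.17), POMC (0.36), CGA (0.36), TIMP1 (0.0571), NEFL (-0.0495), CHGB (0.27), RPL10 (0.12), RPS18 (0.21) and COX7C (0.0273). Reversed under the processed values and the value table alike were estrogen-responsive genes (0.0256), adipokines, orexins and their receptors (0.00292), lymphocyte markers (0.103), posterior and intermediate lobe markers (0.116), NEFL (-0.00601), HBE1 (0.218) and RPS18 (0.0103). Reversed under median centring were activin, inhibin, BMP and TGF-beta signalling (-0.0491), macrophage and myeloid markers (-0.0268) and cell cycle genes (-0.0338). Prostaglandin synthesis and receptors became called without array 1 (-0.279) and stood at -0.0648 without array 3. Unfolded protein response genes became called with the mean of a gene's probes (-0.228) and stood at -0.0820 without array 1. Offset 16 reversed posterior and intermediate lobe markers (0.0180), the mean of a gene's probes KLF2 (-0.0113) and the narrower loess NEFL (-0.0135).

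With 1 array left out, lists that reversed or became called ran from -0.689 to 0.0690 for pituitary hormone genes (called without array 2, adjusted p = 0.0101, and above 0 without array 4, but -0.258 and not called without array 2 and -0.0971 without array 4 once TSHB was left out, a removal chosen after the data were seen), -0.0197 to 0.0607 for activin, inhibin, BMP and TGF-beta signalling, -0.0663 to 0.0211 for adipokines, orexins and their receptors, -0.0497 to 0.111 for macrophage and myeloid markers, -0.0907 to 0.00257 for lymphocyte markers, -0.169 to 0.216 for cell cycle genes (called without array 1), -0.157 to 0.397 for immediate-early genes and -0.116 to 0.209 for heat shock genes (both called without array 3), -0.145 to 0.112 for posterior and intermediate lobe markers and -0.0669 to 0.00156 for oxidative phosphorylation genes. Genes that reversed ran from -1.08 to 0.0187 for GH1, -0.31 to 1.14 for FSHB, -3.27 to 1.06 for TSHB, -0.0681 to 0.025 for C1QB, -0.12 to 0.46 for CCNB1, -0.20 to 0.0267 for AURKB, -0.18 to 0.41 for TOP2A, -0.20 to 1.5 for NR4A3, -0.23 to 0.11 for TIMP1, -0.0405 to 0.26 for ANGPT1, -0.16 to 0.97 for PCSK2, -0.16 to 0.0273 for GLUL, -0.0639 to 0.0752 for NEFL, -0.58 to 0.19 for MBP and -0.13 to 0.11 for HBE1. In these fits the array left alone in its dye orientation counted as much as the others together, so that array could turn a sign. Channels with 50.4% to 66.5% of spots well above background limit what dim probes can show.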

Other observations

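The genes named here were chosen after their values were seen, and no explanation was tested for them. TTR, transthyretin, a carrier of thyroid hormone and retinol, stood at -2.57 ± 0.72, with -4.53, -2.48 and -3.70 on arrays 1, 3 and 4 and 0.44 on array 2 (limma adjusted p = 0.647). RBP4, the retinol-binding protein that circulates with it, stood at -0.66, and CLU, clusterin, at -0.61. ALOX15, a lipoxygenase, stood at 1.05 ± 0.40, from -1.27 on array 2 to 3.09 on array 3. Single arrays carried VRK1, at 3.31 on array 3 and at most 0.53 elsewhere, and SOCS5, at 3.35 on array 3 and at most 0.39 elsewhere. FOS and NR4A2, both immediate-early genes, were at 1.22 and 1.66 on array 1 and at -1.11 and -1.23 on array 2. The immediate-early list as a whole had array means of 0.51, -0.19, -0.60 and 0.76.

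CYP24A1, ITGB3 and MUC13 were among the brightest features, with mean log2 intensities of 18.04, 17.98 and 17.92, and shared a pattern over the arrays. The ratios of CYP24A1, ITGB3 and MUC13 were -2.04, -1.97 and -1.91 on array 1, 1.03, 0.94 and 0.93 on array 2, -0.51, -0.44 and -0.21 on array 3 and 1.62, 1.5 and 1.30 on array 4. Red exceeded green for each of them on all 4 arrays, so the shared pattern followed the dye. Over the 209 features brighter than 16 the median ratios were -0.45, 0.18, -0.08 and 0.20 on arrays 1 to 4. The ribosomal protein genes also followed the dye: their turned means were -0.35 and -0.53 on arrays 1 and 3 and 0.41 and 0.26 on arrays 2 and 4, so red exceeded green on all 4. The 10 spike-in sequences, in the scanner software's processed values, stood at -1.66, -0.31, -0.49 and -0.18 as pregnant over cyclic.

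The feature with the smallest adjusted p carried no gene symbol: BF192668 stood at -1.74 ± 0.10 (limma adjusted p = 0.135). TC574560, also unnamed here, stood at 1.96 ± 0.13 (adjusted p = 0.153) and was above 1.75 on 4 of 4 arrays.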
